A study of Mus musculus with 32 samples.

How the data were processed

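RNA of 8 wild-type SMG, 8 TH-MYCN SMG, 8 primary sphere cultures and 4 passaged sphere cultures was hybridised to one-colour Agilent mouse arrays. Per the labels' protocols, 40 or 200 ng of total RNA with an RNA integrity number over 8 were labelled with Cy3; which sample had which amount is not given in the sources used here, and the extraction text speaks of spheres only. Per the file headers, the arrays were scanned and each spot was read with Agilent Feature Extraction 11.5.1.1. The processed spot intensity deposited for each array is, per the file headers, background-subtracted and spatially detrended within the array and not normalized between arrays. The median intensity of each spot and of its local background, and Agilent's flags per spot, were deposited beside it. The value table deposited by the authors holds log2 values. Set against the scanner files, 99.8% of its values equal the log2 processed signal minus the array's 75th percentile, less a constant per probe, within 0.05. Its scale and direction are therefore known, and the reference of its centring stays unknown. Its column medians were -0.02, -0.24, -0.16, -0.27, -0.48, -0.34, -0.36 and -0.37 in wild-type SMG 1 to 8, -0.13, -0.11, -0.20, -0.33, -0.32, -0.28, -0.39 and -0.24 in TH-MYCN SMG 1 to 8, 0.02, 0.06, 0.07, 0.04, -0.08, 0.01, -0.05 and -0.07 in primary spheres 1 to 8, and 0.31, 0.15, 0.28, 0.30, 0.51, 0.39, 0.45 and 0.35 on the arrays of passaged spheres 1 to 4, 2 arrays each.

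Each array has 62976 features, of which 59305 are not controls, for 55681 distinct probes. Probe accessions were matched without versions to a RefSeq gene table of mouse assembly GRCm38.p6. This named 27235 probes for 20660 symbols and left 28446 unnamed, which were left out of the gene tests. No coordinates were used, since no genome of the array's own build was used here. The analysis ran in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). The main values were log2 processed signal minus the array's 75th percentile. Control spots and spots that Agilent marks as non-uniform or as population outliers (109 to 211 per array) were left out, no spot was saturated, and spots of one probe were averaged. The 2 arrays of a passaged culture were averaged first, so that n = 4. A probe was kept for a comparison if it was well above background in at least 4 of its samples, and a gene was represented by its kept probe with the highest mean. The 75th percentile of signal, which reflects brightness, was 523 to 989 on wild-type SMG arrays, 840 to 1358 on TH-MYCN SMG arrays, 464 to 564 on primary sphere arrays and 323 to 539 on passaged sphere arrays, so dim genes were measured least well in passaged spheres.

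Groups were compared 2 at a time with limma (lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05, and 2-fold means an absolute log2 difference of at least 1. Where no array of the dimmer group had the probe well above background, the fold is a bound ("at least N-fold"): the mean of the brighter group against the mean, over arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal of any probe well above background. Where only some arrays of the dimmer group had the probe well above background, the fitted difference is given without a bound. It then uses signals not well above background, so its size is uncertain and cannot be set beside the bounds. For 26 lists of genes fixed before the data were examined, limma's camera was run with a preset correlation of 0.01 and adjusted over the lists. With an estimated correlation no list was called in any comparison. A list score is the mean of a list's genes in one sample. Named genes follow a rule also fixed before: a panel of 8 genes; the 5 largest rises and 5 largest falls among genes called in every fit without a sample, ranked by fitted values, with a curated symbol and a probe above background on all arrays of the brighter group; and up to 3 members of each called list. Some of these genes are not reported here. Where a gene had several kept probes, none was called in the opposite direction.

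In a test on simulated data with known changes, 50 genes were changed at each size. In the design of TH-MYCN SMG minus wild-type SMG, over 15846 genes, 40% were recovered at a log2 change of 0.5, 66% at 1, 98% at 2 and 100% at 3, and 7.32% of the calls were false. In that of primary sphere minus TH-MYCN SMG, over 15650 genes, 46%, 90%, 98% and 100% were recovered, with 3.47% false. In that of passaged sphere minus primary sphere, over 14243 genes, 50%, 94%, 96% and 98% were recovered, with 4.52% false. In the data 65.6%, 83.2% and 11.7% of the tested genes were called in these 3 comparisons, far more than were changed here. Adjustment is more lenient where many genes change, so these shares can understate the recovery in the data. A list shifted on purpose was called each time and 0 others were. The simulated genes varied independently of each other, so this cannot show how often camera calls lists of correlated genes that did not change.

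The arrays came from 4 slides scanned on 2 days. Slides 1 and 2 each held 4 wild-type and 4 TH-MYCN SMG samples, and slides 3 and 4 each held 4 primary sphere cultures and 1 array of every passaged culture. Within a slide the groups lay in separate rows, so position on the slide cannot be told apart from group. Slide was used as a block, and fits were also run within slides, where a slide held both groups. It was used as a random block for primary spheres against TH-MYCN SMG. For passaged against primary spheres the slide block kept the arrays of passaged cultures apart, with culture as a random block. Other alternatives were normexp background correction with an offset of 50, quantile normalization, the value table deposited by the authors, no filter or a stricter filter on dim probes, all spots kept, the mean of a gene's probes, a variance trend, array weights, all 4 groups in one fit, the replicate number as a block, leaving out each sample, the arrays of passaged cultures kept apart, camera with an estimated correlation, and fry. Normexp ran on the median spot signal, because the mean signal was not among the columns used here. Fits within slides and 2 further scalings, to the median of tested genes and to a median difference of 0, were chosen after the data had been seen.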

Results

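Messenger RNA levels were measured on 32 one-colour microarrays in 4 groups of samples from 3-week-old mice. The superior mesenteric ganglion (SMG), a sympathetic ganglion of the abdomen, was taken from 8 wild-type mice and from 8 TH-MYCN hemizygous mice, which carry a human MYCN gene under a tyrosine hydroxylase promoter and develop neuroblastoma. Spheres are clusters of cells grown in culture, here from TH-MYCN mice. They were measured after 8 days of primary culture in 8 cultures and after 5 passages in 4 cultures, each of these on 2 arrays that were averaged. Each array held 55681 distinct probes, of which 27235 were assigned to 20660 gene symbols. The share of spots well above background was 60.4% to 65.7% on wild-type SMG arrays, 59.1% to 64.1% on TH-MYCN SMG arrays, 57.0% to 59.7% on primary sphere arrays and 49.0% to 53.9% on passaged sphere arrays. Across genes, a sample correlated with the others of its group at a mean of 0.988 in wild-type SMG (n = 8), 0.985 in TH-MYCN SMG (n = 8), 0.989 in primary spheres (n = 8) and 0.988 in passaged spheres (n = 4). The 2 arrays of a passaged culture correlated at 0.993 to 0.994, and arrays of different passaged cultures at 0.980 to 0.989. The highest correlation between separate samples was 0.994 in wild-type SMG, TH-MYCN SMG and primary spheres, as high as between arrays of one culture. No pair held identical values, and the series describes the samples as biological replicates, so all were kept. The number of arrays limits the precision of each value.

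The first comparison set TH-MYCN SMG against wild-type SMG, to ask how the ganglion of mice with the transgene differed before any culture. Genes of cell division were far higher in TH-MYCN SMG. Ccnb1, a cyclin of mitosis, rose by 7.25 on the log2 scale (SE 0.37), from a mean of -3.85 ± 0.89 (SD, n = 8) to 3.40 ± 0.71 (SD, n = 8) relative to the 75th percentile of each array (limma adjusted p = 1.49e-10). Top2a, which untangles DNA, rose by 7.04 (SE 0.41, limma adjusted p = 6.50e-10), and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, by 6.78 (SE 0.27, limma adjusted p = 1.26e-11). Genes of noradrenaline synthesis and storage fell. Th, the rate-limiting enzyme of catecholamine synthesis, fell by 0.84 (SE 0.13, limma adjusted p = 6.01e-05), and Slc6a2, the noradrenaline transporter, fell by 1.09 (SE 0.19, limma adjusted p = 0.000143).

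All 16 measured members of the mitosis list rose, with a median log2 difference of 5.31 (camera adjusted p = 1.05e-17, and adjusted p = 0.327 with an estimated correlation). With the 2 members not well above background in wild-type SMG set to their bounds the median was 5.11. Top2a was well above background on 5 of the 8 wild-type arrays. All 17 members of the DNA replication list rose, with a median of 3.28, or 2.47 with 1 member at its bound (camera adjusted p = 3.00e-16, and adjusted p = 0.350 with an estimated correlation). Among them were Rrm2, a subunit of ribonucleotide reductase (5.54, SE 0.27), Cdc6 (4.35, SE 0.28) and Mcm6, part of the replicative helicase (4.26, SE 0.23). Of 17 ribosome biogenesis genes 15 rose, with a median of 0.78 (camera adjusted p = 3.11e-07, and adjusted p = 0.416 with an estimated correlation), for example Fbl (1.28, SE 0.14), Nop58 (1.25, SE 0.16) and Ppan (1.19, SE 0.16). The counts adjusted over the list alone were 16 for mitosis, 17 for DNA replication and 15 for ribosome biogenesis. Within slides 1 and 2 the medians were 5.13 and 5.61 for mitosis, 3.16 and 3.36 for DNA replication, and 0.90 and 0.76 for ribosome biogenesis.

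Of 14 genes of nucleotide and polyamine synthesis 8 rose and 1 fell (median 0.39, camera adjusted p = 0.00135, and adjusted p = 0.580 with an estimated correlation). Shmt1 rose by 5.55 (SE 0.34) and was well above background on 2 of the 8 wild-type arrays, while another probe for Shmt1 differed by 0.26 (limma adjusted p = 0.116). Impdh2 rose from 3.13 ± 0.13 (SD, n = 8) to 4.23 ± 0.40 (SD, n = 8). Cad rose by 1.21 (SE 0.22), a call that ended with the normexp background (0.27, adjusted p = 0.203). Of 10 components of PRC2, the complex that methylates histone H3, 8 rose and 1 fell (median 0.73, camera adjusted p = 0.000205, and adjusted p = 0.416 with an estimated correlation). Ezh2, its catalytic subunit, rose by 3.04 (SE 0.21), Phf19 by 1.77 (SE 0.21) and Mtf2 by 1.30 (SE 0.14). The counts adjusted over the list alone were 9 for nucleotide and polyamine synthesis and 9 for PRC2. Within slides 1 and 2 their medians were 0.55 and 0.25, and 0.82 and 0.63.

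All 13 measured genes of catecholamine synthesis and storage fell, with a median of -0.82 (camera adjusted p = 0.00128, and adjusted p = 0.627 with an estimated correlation). Besides Th and Slc6a2 they included Scg2 (-1.10, SE 0.17) and Npy, a neuropeptide stored with noradrenaline (-0.97, SE 0.15). Of 19 mature neuron genes 15 fell (median -0.62, camera adjusted p = 0.0219, and adjusted p = 0.627 with an estimated correlation). Among them were Chrnb4, a nicotinic receptor subunit (-1.32, SE 0.22), and Prph, an intermediate filament of peripheral neurons (-1.06, SE 0.21). Of 15 cholesterol synthesis genes 13 fell (median -0.86, camera adjusted p = 0.00604, and adjusted p = 0.679 with an estimated correlation), among them Insig1 (-1.06, SE 0.22) and Fdft1 (-0.95, SE 0.13). The counts adjusted over the list alone were 13, 15 and 14. The mature neuron list was not called with the normexp background (median -0.58, adjusted p = 0.0998) or after quantile normalization (-0.58, adjusted p = 0.0559). Relative to the median of all tested genes, which lay at -0.22, the medians of these 3 lists were -0.60, -0.41 and -0.64. Within slides 1 and 2 the medians were -0.82 and -0.81 for catecholamine genes, -0.61 and -0.64 for mature neuron genes, and -0.66 and -0.94 for cholesterol synthesis.

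**Figure D1:**
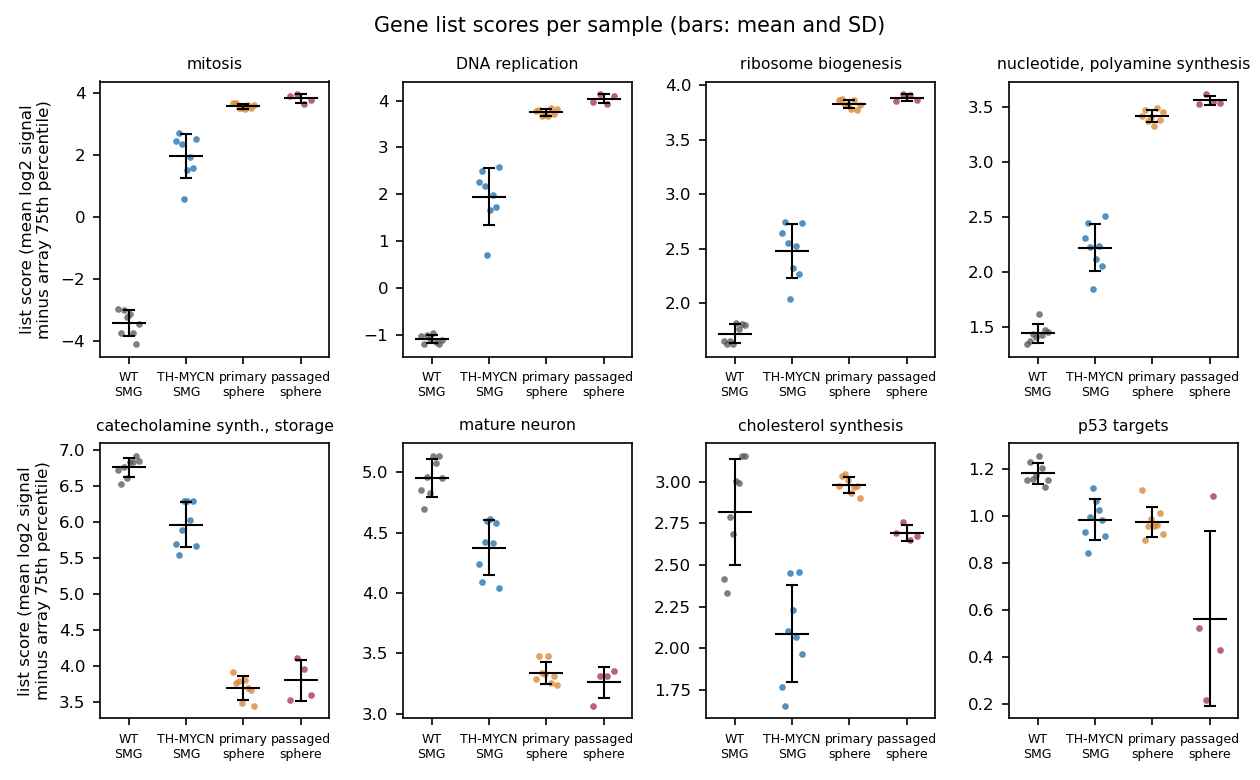
Scores of 8 gene lists in each sample, as the mean log2 signal of a list's genes relative to the 75th percentile of the array (vertical axes, which differ between panels), for 8 wild-type SMG, 8 TH-MYCN SMG, 8 primary sphere cultures and 4 passaged sphere cultures; points are samples, and bars are the mean and SD. The mitosis score lies between -4.12 and -2.97 in wild-type SMG, between 0.58 and 2.71 in TH-MYCN SMG and between 3.47 and 3.68 in primary spheres, while the catecholamine score has means of 6.75, 5.96 and 3.69.

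Markers of other cell types moved beside these groups. Of 14 markers of Schwann and satellite glia 10 fell and 1 rose (median -0.87, camera adjusted p = 0.0272, and adjusted p = 0.627 with an estimated correlation; 12 adjusted over the list alone). Among those that fell were S100b (-1.62, SE 0.15) and Mag (-1.24, SE 0.19). Of 11 macrophage markers 8 rose and 2 fell (median 1.35, camera adjusted p = 0.00521, and adjusted p = 0.627 with an estimated correlation; 10 adjusted over the list alone). Aif1 rose by 1.78 (SE 0.17) and C1qc by 1.48 (SE 0.17), and Tyrobp rose from 1.67 ± 0.33 (SD, n = 8) to 3.17 ± 0.43 (SD, n = 8). The glial list had a median of -1.04 within slide 1 and -0.78 within slide 2, where it was not called (adjusted p = 0.0693). With all 4 groups in one fit it was not called either (adjusted p = 0.220). The macrophage list had 1.17 within slide 1, where it was not called (adjusted p = 0.0605), and 1.47 within slide 2. Markers of fibroblasts (median -0.64, camera adjusted p = 0.115), smooth muscle and pericytes (-0.72, 0.0763) and endothelium (-0.51, 0.0913) were not called as lists, although 9 of 12, 8 of 9 and 9 of 12 members fell. Within slide 1 all 3 were called lower (-0.86, -1.15 and -0.81, adjusted p = 0.0173, 0.0204 and 0.0110), and the smooth muscle list was called without wild-type SMG 7 (adjusted p = 0.0342).

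The remaining lists were not called. These were sympathoadrenal transcription factors (camera adjusted p = 0.113), mesenchymal-type neuroblastoma factors (0.238), p53 targets (0.766), hypoxia and glycolysis (0.353), the amino acid stress response (0.713), immediate early genes (0.766), and markers of lymphocytes (0.766), pancreatic acini (0.313), adrenal cortex (0.766), erythroid cells (0.766), and mesothelium and epithelium (0.766). Neural crest and progenitor genes and adipocyte markers were not called either (camera adjusted p = 0.63 each). The erythroid median was -0.11 although the test leaned higher. Sympathoadrenal factors were called higher within slide 1 (median 0.29, adjusted p = 0.0255).

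Of the panel chosen for neuroblastoma, Alk, a receptor tyrosine kinase mutated in some neuroblastomas, rose by 4.51 (SE 0.30, limma adjusted p = 3.67e-09). Mycl rose by 3.00 (SE 0.34) and Lin28b by 0.54 (SE 0.12). Myc fell by 0.63 (SE 0.10). Dbh, which makes noradrenaline, fell by 0.54 (SE 0.11), a call that ended after quantile normalization (-0.18, adjusted p = 0.0884). The mouse Mycn probe, which need not detect the human transgene, read 1.00 ± 0.12 (SD, n = 8) in TH-MYCN SMG and 1.30 ± 0.36 (SD, n = 8) in wild-type SMG and missed the threshold (limma adjusted p = 0.0632). It was called lower with the slide as a block (adjusted p = 0.0491) and within slide 2 (-0.53, adjusted p = 0.0214). It was also called without wild-type SMG 2 (0.0176), wild-type SMG 1 (0.0362) or TH-MYCN SMG 4 (0.0432), and in other fits that pool or weight the samples differently.

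Genes named for large fitted rises were Pnoc, the precursor of nociceptin (at least 699-fold, limma adjusted p = 4.78e-12), Igfbpl1 (9.52, SE 0.50), Pbk, a mitotic kinase (7.54, SE 0.35), Ush1c (at least 62.1-fold, limma adjusted p = 4.32e-12) and Insm1, a transcription factor of neuroendocrine progenitors (7.46, SE 0.32). Igfbpl1 was well above background on 1 and Pbk on 4 of the 8 wild-type arrays, so the sizes of their rises rest partly on undetected signals. Genes named for large fitted falls were Mcpt-ps1 (-2.93, SE 0.49), Vmn1r240 (-2.89, SE 0.40), Mcpt4 (-2.45, SE 0.26), Myo1h (-2.44, SE 0.39) and Cma1 (-2.36, SE 0.29), of which Mcpt4 and Cma1 encode mast cell proteases. In TH-MYCN SMG, Mcpt-ps1 and Myo1h were well above background on 6, Cma1 on 5 and Vmn1r240 on 1 of 8 arrays.

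Among the 8 TH-MYCN SMG, samples with a higher mitosis score had a lower catecholamine score (r = -0.895, exact permutation p = 0.00102, adjusted p = 0.00356 over 7 relations; rho = -0.976, exact permutation p = 3.97e-04). Without the 2 samples farthest from the median mitosis score r was -0.983, and after centring within slides it was -0.93 (exact permutation p = 0.00174). This relation was chosen after the scores had been seen.

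**Figure D2:**
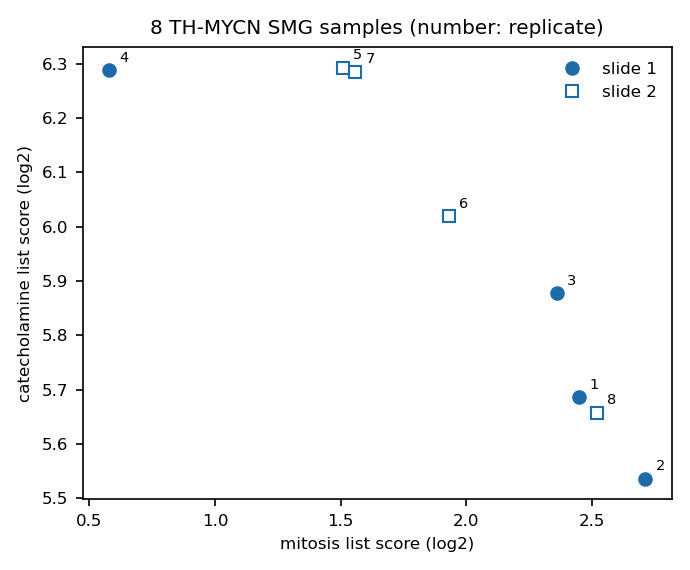
Catecholamine score against mitosis score in the 8 TH-MYCN SMG, both as mean log2 signal of a list's genes relative to the 75th percentile of the array, with 1 point per sample. The catecholamine score lies between 5.54 and 6.29 and the mitosis score between 0.58 and 2.71 (r = -0.895).

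Of 15846 genes tested, 3476 were higher and 6912 lower in TH-MYCN SMG, 1240 and 969 of them at least 2-fold, and 9439 were called whichever sample was left out. With the slide as a block 3699 were higher and 7533 lower, within slide 1 2796 and 4717, and within slide 2 3082 and 6681. No gene was called in opposite directions by these fits, and every list called above was called with the block, at the same median. Each slide held equal numbers of both groups, so by design the block left the fitted differences, and thus the medians, as they were. The split of the calls depended on the scaling, since 33.5% of the calls were higher as reported and 54.4% (5143 higher, 4317 lower) once arrays were shifted so that the median gene did not differ.

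The comparison of primary spheres with TH-MYCN SMG asked which cells and programs of the ganglion were present after 8 days of culture. Transcripts of connective tissue, blood and immune cells were far lower in primary spheres. Dcn, a proteoglycan of fibroblasts, fell by 12.35 on the log2 scale (SE 0.41, limma adjusted p = 6.10e-14), from 6.22 ± 0.13 (SD, n = 8) to -6.13 ± 1.23 (SD, n = 8). It was well above background on 2 of the 8 sphere arrays, so the size of this fall rests mostly on undetected signals. C1qc, a complement gene of macrophages, was at least 215-fold lower (limma adjusted p = 1.73e-18) and Hbb-b2, a beta globin, at least 1252-fold lower (limma adjusted p = 9.03e-14). Mouse Mycn was higher in spheres by 2.61 (SE 0.08, limma adjusted p = 1.45e-14) and Lin28b by 1.76 (SE 0.11).

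Several lists of markers of other cell types fell. The macrophage list fell in all 11 members (median -7.51, or -6.32 with 7 members at their bounds, camera adjusted p = 4.54e-08, and adjusted p = 0.0706 with an estimated correlation). Tyrobp (-10.32, SE 0.41) and Aif1 (-9.86, SE 0.34) were well above background on 1 of 8 sphere arrays each. Apart from primary sphere 6 (-4.28), Tyrobp read -7.77 to -7.39 in primary spheres, below the lowest signal well above background there (-5.56 to -5.22 by array). The sizes of these 2 falls, and of those below for genes seen on few sphere arrays, thus rest mostly on undetected signals. The erythroid list fell in all 6 members (median -10.68, or -10.35 with 2 at their bounds, camera adjusted p = 0.000565, and adjusted p = 0.282 with an estimated correlation), with Hbb-bt (-11.84, SE 0.62) and Hba-a1 (-10.95, SE 0.53) above background on 1 sphere array each. The fibroblast list fell in 11 of 12 members and rose in 1 (median -5.87, or -4.96 with 2 at their bounds, camera adjusted p = 0.000108, and adjusted p = 0.282 with an estimated correlation), with Mgp (-9.55, SE 0.80) and Lum (-9.15, SE 0.67) above background on 3 of 8 sphere arrays each. Endothelial markers fell in 11 of 12 and rose in 1 (median -3.03, or -2.73 with 3 at their bounds, camera adjusted p = 0.000109, and adjusted p = 0.282 with an estimated correlation). Cldn5 was at least 23.1-fold and Cdh5 at least 15.9-fold lower, and Emcn (-5.25, SE 0.38) was above background on 1 sphere array.

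Smooth muscle and pericyte markers fell in all 8 (median -2.35, or -1.93 with 3 at their bounds, camera adjusted p = 0.00105, and adjusted p = 0.282 with an estimated correlation). Actg2 was at least 8.31-fold lower, Rgs5 fell by 2.48 (SE 0.14), and Acta2 fell from -1.70 ± 0.40 (SD, n = 8) to -5.69 ± 0.55 (SD, n = 8), above background on 2 sphere arrays. Glial markers fell in 12 of 14 and rose in 1 (median -2.87, the same with 2 at their bounds, camera adjusted p = 0.000563, and adjusted p = 0.282 with an estimated correlation). S100b (-5.32, SE 0.71), Cdh19 (-5.24, SE 0.72) and Foxd3 (-4.89, SE 0.81) were each above background on 4 of the 8 sphere arrays. These falls are averages over cultures that stood apart by slide, with glial scores of -1.66 ± 0.32 (SD, n = 4) on slide 3 and -3.27 ± 0.08 (SD, n = 4) on slide 4, and fibroblast scores of -1.93 ± 0.53 and -3.89 ± 0.34. Adipocyte markers fell in 7 of 9 (median -3.55, or -1.996 with 5 at their bounds, camera adjusted p = 0.00750, and adjusted p = 0.446 with an estimated correlation), with Fabp4 at least 122-fold, Cfd at least 128-fold and Cidec at least 11.1-fold lower. Cidec was above background on 7 of the 8 TH-MYCN SMG arrays. The counts adjusted over the list alone were 11 for macrophages, 6 for erythroid cells, 12 for fibroblasts, 12 for endothelium, 8 for smooth muscle, 13 for glia and 7 for adipocytes. Markers of lymphocytes (camera adjusted p = 0.113), pancreatic acini (0.706), adrenal cortex (0.583), and mesothelium and epithelium (0.0994) were not called.

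**Figure D3:**
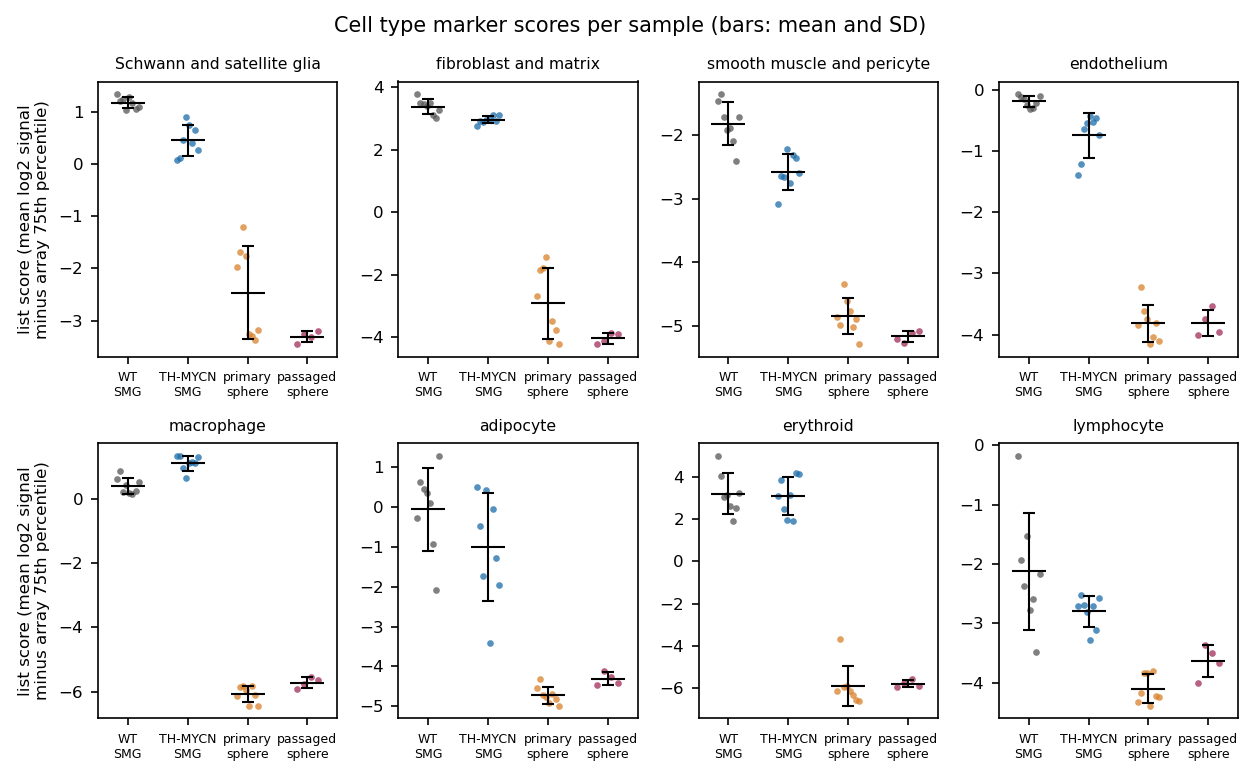
Scores of 8 lists of cell type markers in each sample, drawn as in the plot of gene programs (log2 relative to the 75th percentile of the array, vertical axes differ between panels, points are samples, bars are the mean and SD). The macrophage score lies at a mean of 0.40 in wild-type SMG, -6.06 in primary spheres and -5.71 in passaged spheres and spans 0.63 to 1.33 in TH-MYCN SMG, and the glial score spans -3.36 to -1.20 among primary spheres and -3.45 to -3.20 among passaged spheres. Both sphere means of the macrophage score lie below the lowest signal well above background on every sphere array. That signal was -5.56 to -5.22 on primary and -5.05 to -4.11 on passaged sphere arrays, so the difference between these means is not a measured change.

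Genes of growth were higher in spheres than in TH-MYCN SMG. All 17 ribosome biogenesis genes rose (median 1.39, camera adjusted p = 0.000108, and adjusted p = 0.282 with an estimated correlation), led by Fbl (1.72, SE 0.15), Npm1 (1.64, SE 0.13) and Ncl (1.56, SE 0.13). All 16 mitosis genes rose (median 1.62, camera adjusted p = 0.00640, and adjusted p = 0.533 with an estimated correlation). Among them were Ube2c (2.01, SE 0.25), Cdk1 (1.99, SE 0.27) and Aurkb (2.18, SE 0.63, above background on 4 of 8 SMG arrays), and the call of Cdk1 ended with all 4 groups in one fit (adjusted p = 0.0856). All 17 DNA replication genes rose (median 1.79, camera adjusted p = 0.000565, and adjusted p = 0.446 with an estimated correlation), led by Cdt1 (2.11, SE 0.23), Rrm2 (2.07, SE 0.25) and Mcm3 (1.99, SE 0.22). Nucleotide and polyamine synthesis rose in 13 of 14 genes (median 1.25, camera adjusted p = 0.000563, and adjusted p = 0.282 with an estimated correlation), led by Odc1 (1.89, SE 0.14), Shmt1 (1.88, SE 0.24) and Ppat (1.81, SE 0.09). The counts adjusted over the list alone were 17, 16, 17 and 13.

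Cholesterol synthesis rose in 13 of 15 genes (median 0.67, camera adjusted p = 0.00750, and adjusted p = 0.446 with an estimated correlation; 13 adjusted over the list alone). Mvd (1.67, SE 0.14) and Lss (1.66, SE 0.11) rose most. The amino acid stress response rose in 9 of 12 and fell in 1 (median 0.88, camera adjusted p = 0.0421, and adjusted p = 0.282 with an estimated correlation; 10 adjusted over the list alone). Mthfd2, Psat1 and Shmt2, enzymes of serine and one-carbon metabolism, rose by 2.04 (SE 0.10), 1.95 (SE 0.15) and 1.90 (SE 0.11). That list lost its call without TH-MYCN SMG 1 (adjusted p = 0.0524) or TH-MYCN SMG 2 (0.0503). It also lost it with the normexp background (median 0.83, adjusted p = 0.130), quantile normalization (0.89, 0.0926), a strict filter on dim probes (0.88, just over 0.05) and array weights (0.92, 0.0602). Relative to the median of all tested genes, which lay at 0.27, the medians were 0.40 for cholesterol synthesis, 0.61 for the amino acid stress response, 1.35 for mitosis and 1.12 for ribosome biogenesis.

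Of 13 catecholamine genes 11 fell and 1 rose (median -2.05, camera adjusted p = 0.000108, and adjusted p = 0.282 with an estimated correlation; 12 adjusted over the list alone). Npy (-7.38, SE 0.22), Slc6a2 (-5.28, SE 0.23) and Slc18a2, the vesicular monoamine transporter (-3.09, SE 0.15), fell most, and Dbh fell by 2.05 (SE 0.10). Th read 7.81 ± 0.15 (SD, n = 8) in spheres and 7.72 ± 0.34 (SD, n = 8) in TH-MYCN SMG, a difference of 0.09 that did not pass the test (limma adjusted p = 0.542). After quantile normalization that difference was -0.90 (limma adjusted p = 6.00e-05). Neural crest and progenitor genes fell in 10 of 16 and rose in 2 (median -1.22, or -1.13 with 2 at their bounds, camera adjusted p = 0.00909, and adjusted p = 0.331 with an estimated correlation; 12 adjusted over the list alone). With the normexp background this list was not called (median -0.28, adjusted p = 0.103). Among them Ngfr, a neurotrophin receptor, fell by 5.36 (SE 0.33), Prom1 fell by 3.97 (SE 0.18) and Snai2 was at least 9.01-fold lower. Mesenchymal-type neuroblastoma factors fell in 8 of 9 and rose in 1 (median -3.50, or -2.90 with 3 at their bounds, camera adjusted p = 0.00180, and adjusted p = 0.282 with an estimated correlation; 9 adjusted over the list alone). Meox2 was at least 41.2-fold and Meox1 at least 7.44-fold lower, and Yap1 (-6.13, SE 0.88) was above background on 5 of 8 sphere arrays.

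Sympathoadrenal transcription factors (camera adjusted p = 0.642), mature neuron genes (0.217), PRC2 (0.0575), p53 targets (0.706), hypoxia and glycolysis (0.133) and immediate early genes (0.709) were not called as lists. PRC2 was called higher without TH-MYCN SMG 4 (adjusted p = 0.0444) or 8 (0.0417). The medians of sympathoadrenal factors (0.25), immediate early genes (0.08) and acinar markers (0.02) were above 0 although their tests leaned lower. Genes named for large fitted rises were Pantr1 (6.14, SE 0.62, above background on 7 of 8 SMG arrays), Lhx3 (at least 20.6-fold, limma adjusted p = 8.61e-13), Npffr1, a neuropeptide receptor (at least 23.6-fold, limma adjusted p = 4.98e-13), Ntf3, the growth factor neurotrophin-3 (5.49, SE 0.23), and Vip, vasoactive intestinal peptide (5.34, SE 0.53). H2-Ab1, which presents antigen in MHC class II, fell as well (at least 469-fold lower, limma adjusted p = 6.82e-17). Alk rose by 0.71 (SE 0.25, limma adjusted p = 0.0141), a call that ended after quantile normalization (0.46, adjusted p = 0.113) and after shifting the median gene to 0 (0.44, adjusted p = 0.121). Myc fell by 2.55 (SE 0.29, above background on 5 of 8 sphere arrays), and the difference of Mycl was -0.05 (limma adjusted p = 0.851).

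Of 15650 genes tested, 7863 were higher and 5156 lower in primary spheres, 2515 and 3382 of them at least 2-fold, and 12519 were called whichever sample was left out. Every slide held either SMG or sphere arrays, and each kind was scanned on a day of its own, so scan day cannot be told apart from the groups. With slide as a random block 7510 were higher and 4908 lower, and every list called above was called, at the same median. The equal medians follow from equal numbers of arrays per slide. Such a block cannot remove slide differences between these groups. Quantile normalization moved the median of all genes by -0.17 and scaling to the median of tested genes by 0.12. The share of calls that were higher was 60.4% as reported and 48.3% (5897 higher, 6323 lower) after the median gene was set to 0.

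These 2 comparisons share the TH-MYCN SMG samples, and 15466 genes were tested in both. Of these 6421 were called in the same direction, 2685 higher and 3736 lower in both steps, and 2180 in opposite directions. Independent lists of these lengths would share 1733 and 2229 genes in the same direction. When the TH-MYCN SMG samples were split between the comparisons, 5904 and 5497 genes were called in the same direction. Simulated groups with no change were drawn from the spread within groups of the first comparison, with a shared middle group. They gave 0 genes called the same way with limma. At an unadjusted p under 0.05 they gave 0.6 the same way and 145.95 in opposite directions (mean of 20 draws). With nothing changed, adjustment leaves almost no calls, and the shared group enters with opposite sign. The 0 was therefore nearly fixed in advance and gives no support to the 6421.

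The third comparison set passaged spheres against primary spheres, to ask what changed over 5 passages. Cidea, a lipid droplet protein, rose by 2.23 on the log2 scale (SE 0.32, limma adjusted p = 0.00200), from -0.41 ± 0.35 (SD, n = 8) to 1.81 ± 0.89 (SD, n = 4). Fabp7, a fatty acid binding protein of glia, was at least 27.0-fold lower (limma adjusted p = 0.00115). Sparc, a matrix protein, fell by 5.78 (SE 1.24, limma adjusted p = 0.0137), from 2.96 ± 2.61 (SD, n = 8) to -2.81 ± 0.81 (SD, n = 4), with 7 of 8 passaged arrays above background. Within slide 3 Sparc differed by -7.90 (limma adjusted p = 7.49e-05) and within slide 4 by -3.65 (0.0171), and another probe for it was not called (-3.23, adjusted p = 0.127). Primary spheres had means of 5.36 on slide 3 and 0.57 on slide 4 for Sparc, and of 1.83 and -1.52 for Fabp7. Dbh rose by 0.66 (SE 0.12, limma adjusted p = 0.00613).

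Sympathoadrenal transcription factors rose in 5 of 16 members and fell in 3 (median 0.40, camera adjusted p = 0.00758, and adjusted p = 0.280 with an estimated correlation; 14 adjusted over the list alone). Insm1 rose by 0.95 (SE 0.14, limma adjusted p = 0.00199), Gata3 by 0.77 (SE 0.16) and Gata2 by 1.83 (SE 0.45, limma adjusted p = 0.0243). The call of Gata2 was lost without passaged sphere 2 (0.0564) or 4 (0.0805). The list was not called without a filter on dim probes (adjusted p = 0.251). DNA replication genes rose in 8 of 17 (median 0.29, camera adjusted p = 2.37e-07, and adjusted p = 0.187 with an estimated correlation; 12 adjusted over the list alone), among them Cdt1 (0.59, SE 0.12), Mcm3 (0.47, SE 0.09) and Mcm6 (0.37, SE 0.07). Of 16 mitosis genes 2 rose (median 0.24, camera adjusted p = 7.66e-05, and adjusted p = 0.280 with an estimated correlation; 9 adjusted over the list alone). They were Mki67 (0.35, SE 0.09, limma adjusted p = 0.0259) and Plk1 (0.34, SE 0.10, limma adjusted p = 0.0440). Mki67 was lost without passaged sphere 1, 2 or 4 (0.0654, 0.0870 and 0.0650). Plk1 was lost without primary sphere 1, 2, 3, 4, 5 or 7 or passaged sphere 1 or 2 (0.0534 to 0.133). The mitosis list was not called with all 4 groups in one fit (adjusted p = 0.0900). Within slides 3 and 4 the medians were 0.37 and 0.43 for sympathoadrenal factors, 0.29 and 0.30 for DNA replication, and 0.26 and 0.23 for mitosis.

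Of 14 nucleotide and polyamine genes 1 rose, Impdh2 (0.27, SE 0.07, limma adjusted p = 0.0271), with a list median of 0.15 (camera adjusted p = 0.00914, and adjusted p = 0.197 with an estimated correlation; 4 adjusted over the list alone). Impdh2 was lost without primary sphere 4 or 7 or passaged sphere 1, 2 or 4 (0.0503 to 0.0757). PRC2 components rose in 3 of 10 and fell in 1 (median 0.16, camera adjusted p = 0.0159, and adjusted p = 0.187 with an estimated correlation; 6 adjusted over the list alone). Phf19 (1.05, SE 0.22), Ezh2 (0.33, SE 0.06) and Aebp2 (0.36, SE 0.10, limma adjusted p = 0.0389) rose, and Aebp2 was lost without primary sphere 3, 4, 5, 6 or 7 or any passaged sphere (0.0564 to 0.0877). Neither list was called with the normexp background (medians 0.12 and 0.10, adjusted p = 0.0529 and 0.0717) or without a filter on dim probes (adjusted p = 0.251 and 0.251). Within slides 3 and 4 the medians were 0.11 and 0.15 for nucleotide and polyamine genes and 0.17 and 0.26 for PRC2. Other probes of Aebp2 (0.27, adjusted p = 0.0712) and Mki67 (0.26, adjusted p = 0.0698) were not called.

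Cholesterol synthesis genes fell in 6 of 15 (median -0.27, camera adjusted p = 5.65e-06, and adjusted p = 0.0947 with an estimated correlation; 11 adjusted over the list alone), led by Mvd (-0.77, SE 0.09), Nsdhl (-0.60, SE 0.10) and Lss (-0.46, SE 0.08). Another probe of Nsdhl was not called (-0.41, adjusted p = 0.0571). Of 13 p53 targets 5 fell (median -0.25, or -0.15 with 1 member at its bound, camera adjusted p = 0.00758, and adjusted p = 0.280 with an estimated correlation; 5 adjusted over the list alone). The passaged cultures did not all share this fall: the p53 score was 1.09 in passaged sphere 3 and 0.22 to 0.53 in the other 3, against 0.90 to 1.11 in primary spheres. Fas, a death receptor, was at least 1.11-fold lower (limma adjusted p = 5.22e-05) and Gdf15 (-1.34, SE 0.22) was above background on 1 of 8 passaged arrays. With the normexp background the calls of Fas (-0.19, adjusted p = 0.333) and Gdf15 (-0.18, adjusted p = 0.388) ended. Trp53inp1 (-1.06, SE 0.25, limma adjusted p = 0.0190) was lost without passaged sphere 2 (0.0594) or 4 (0.0661). Within slides 3 and 4 the medians were -0.39 and -0.20 for cholesterol synthesis and -0.24 and -0.16 for p53 targets, the last not called (adjusted p = 0.0611).

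The amino acid stress response fell in 2 of 12, Phgdh (-1.50, SE 0.24) and Chac1 (-0.43, SE 0.08), with a list median of -0.09 (camera adjusted p = 0.0457, and adjusted p = 0.187 with an estimated correlation; 2 adjusted over the list alone). It was not called without primary sphere 1, 2, 3 or 4 or passaged sphere 1 or 4 (adjusted p = 0.0502 to 0.117). Of 3 measured smooth muscle and pericyte markers 2 fell, with a median of -2.02, or -1.52 with 1 at its bound (camera adjusted p = 0.0146, and adjusted p = 0.187 with an estimated correlation; 2 adjusted over the list alone). They were Rgs5 (-2.50, SE 0.22, above background on 1 of 8 passaged arrays) and Pdgfrb, at least 2.87-fold lower (limma adjusted p = 0.00370), a call that ended with the normexp background (-0.48, adjusted p = 0.0795). The smooth muscle list was not called with the normexp background (median -0.48, adjusted p = 0.0529) or without a filter on dim probes (0.17, adjusted p = 0.243). Within slide 3 the medians were -0.16 for the amino acid stress response and -2.45 for smooth muscle. Within slide 4 both lists were not called (-0.13, adjusted p = 0.327, and -1.60, adjusted p = 0.0727).

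Markers of glia and fibroblasts moved with the slide. Within slide 3 the glial list (median -1.67, adjusted p = 9.93e-05) and the fibroblast list (median -3.26, adjusted p = 0.0184) were lower in passaged spheres. Within slide 4 they were not called (0.19, adjusted p = 0.797, and -0.70, adjusted p = 0.552). Over both slides 3 of 12 glial and 2 of 7 fibroblast markers fell and 1 and 2 rose (medians -0.81 and -2.15, camera adjusted p = 0.159 and 0.403, not called). Mesenchymal-type factors (-1.01, adjusted p = 0.00401), hypoxia and glycolysis (-0.22, adjusted p = 0.0462) and endothelium (-0.36, adjusted p = 0.0462) were also called lower within slide 3 alone.

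The remaining lists were not called over both slides. These were the catecholamine genes (camera adjusted p = 0.328), mature neuron genes (0.828), neural crest and progenitor genes (0.547), mesenchymal-type factors (0.159), ribosome biogenesis (0.303), hypoxia and glycolysis (0.0774), immediate early genes (0.828), and markers of endothelium (0.159), macrophages (0.796), lymphocytes (0.547), adipocytes (0.547), pancreatic acini (0.0774), adrenal cortex (0.817), erythroid cells (0.870), and mesothelium and epithelium (0.534). Hypoxia and glycolysis was called lower without primary sphere 8 (adjusted p = 0.0384) and acinar markers without primary sphere 5 (0.0389). The median of mature neuron genes was 0.07 although the test leaned lower.

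Other large rises were those of Maob, a monoamine oxidase (1.92, SE 0.28), Kitl (1.74, SE 0.30), Dsc2 (1.74, SE 0.27) and Rbm24 (1.63, SE 0.26). Other large falls were those of Dsel (at least 11.0-fold, limma adjusted p = 1.09e-08), Gpm6a (-5.02, SE 0.74, above background on 2 of 8 passaged arrays) and Selenop (-4.83, SE 1.07, on 1 of 8). The call of Selenop ended with the normexp background (-1.95, adjusted p = 0.0938). Mouse Mycn rose by 0.44 (SE 0.10, limma adjusted p = 0.0144), a call lost without passaged sphere 2 (0.0542) and within slide 4 (0.44, adjusted p = 0.0653). Th (0.26, limma adjusted p = 0.116), Alk (0.14, 0.563), Lin28b (0.26, 0.128), Myc (0.39, 0.571) and Mycl (-0.48, 0.289) were not called, although Myc was called higher within slide 4 (1.00, adjusted p = 0.0384).

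Of 14243 genes tested, 732 were higher and 931 lower in passaged spheres, 41 and 340 of them at least 2-fold, and 622 were called whichever sample was left out. With slide as a block 1091 were higher and 1110 lower, within slide 3 274 and 765, and within slide 4 469 and 490. The fit with the block kept the 2 arrays of each passaged culture apart, with culture as a random block (correlation 0.787). Its slide term drew mostly on those pairs of arrays, so it cannot fully remove a difference between primary spheres of the 2 slides. Every list called over both slides was called with the block, at the same median. The groups were balanced over the slides, so by design the block left the fitted differences as they were. Of the 34 named genes called here, 34 were called with the block, 24 within slide 3 and 28 within slide 4, all in the same direction. Within slide 3 the calls of Dsc2 (1.42, adjusted p = 0.110), Gata2 (1.62, 0.156), Mki67 (0.31, 0.184), Plk1 (0.27, 0.150), Mcm3 (0.38, 0.0723), Mcm6 (0.34, 0.0545), Impdh2 (0.19, 0.141), Phf19 (1.01, 0.110), Aebp2 (0.22, 0.110) and Trp53inp1 (-1.09, 0.131) ended. Within slide 4 those of Mycn, Gata2 (2.03, adjusted p = 0.0702), Mki67 (0.40, 0.0739), Plk1 (0.42, 0.0872), Phf19 (1.09, 0.0577) and Trp53inp1 (-1.03, 0.0742) ended. Without passaged sphere 2 or 4 the number of higher genes fell to 258 and 263, and without primary sphere 4 or 7 to 436 and 447.

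The third comparison shares the primary spheres with the one before it, and 14225 genes were tested in both. Of these 369 moved in opposite directions, 237 higher and then lower and 132 lower and then higher, where independent lists of these lengths would share 514 and 199. A further 1083 moved the same way, 506 higher and 577 lower in both steps, where independent lists would share 403 and 254. With the primary spheres split between the comparisons, 258 and 217 genes moved in opposite directions. Simulated groups with no change, drawn from the spread within groups of the earlier comparison, gave 0 genes in opposite directions with limma. At an unadjusted p under 0.05 they gave 107.6 (mean of 20 draws), since the shared group enters with opposite sign. With nothing changed, adjustment leaves almost no calls, so the 0 does not weigh on the 369.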

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

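The counts over other splits of the samples and the comparison of slides within passaged cultures were laid down before their results were seen, while the 3 patterns weighed here were picked from the scores of each sample and all their other tests were chosen after that. The real split of each comparison was the only 1 of 100 splits into groups of the same sizes that called as many genes. This argues against a chance split of the samples but does not exclude it, since only some of the possible splits were drawn. Ganglia and cultured spheres differ so widely that mixed splits of them could hardly call a gene, so that result was nearly fixed in advance. Nor can these splits tell group apart from row on the slide, or from scan day in spheres against SMG. For TH-MYCN SMG against wild-type SMG 10388 genes were called and at most 5183 in another split, one with 6 of the 8 samples of a group on the same side. For primary spheres against TH-MYCN SMG these were 13019 and 0, and for passaged against primary spheres 1663 and 28. The split of the SMG by slide (slide 1 against slide 2) called 1232 genes, fewer than the real one. Primary spheres of slide 3 against all other spheres gave 752. That split pools primary spheres of slide 4 with passaged ones, so its count does not measure the slide difference. Primary spheres of slide 3 directly against those of slide 4 had 1173 genes higher and 626 lower, 439 and 12 by at least 2-fold. Passaged against primary spheres had 732 and 931, 41 and 340 by at least 2-fold.

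Among primary spheres, glial and fibroblast marker scores were higher in the 4 cultures of slide 3 than in the 4 of slide 4, at -1.66 ± 0.32 against -3.27 ± 0.08 (SD) for glia and -1.93 ± 0.53 against -3.89 ± 0.34 for fibroblasts (exact permutation p = 0.0286 each, the smallest possible, adjusted p = 0.106 over 26 lists), and 1173 genes were called higher and 626 lower with limma. The slide or hybridisation batch is argued against by the passaged cultures, each of which had an array on both slides: of the members above background on all of their arrays, the 5 that differed by over 0.5 between the primary spheres of the slides (median 2.01) differed there by a median of 0.0933 (0.0163 to 0.215 by culture). More glial and fibroblast cells in the cultures on slide 3 would also raise their transcripts outside the 2 lists, and of 32 further markers bright in TH-MYCN SMG 23 lay higher in all 4 cultures of slide 3 than in any of slide 4, against 12.9% of all tested genes, among them Apoe (means of 2.98 and 0.37), Nid1 (1.34 and -3.27) and Col6a1 (-0.72 and -3.40). That remains a candidate explanation. A shared culture session or labelling run stays open as well, and the design names no difference between these cultures.

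Catecholamine, mature neuron and glial lists were lower in TH-MYCN SMG than in wild-type SMG (score differences of -0.80, -0.58 and -0.72). Array scaling is argued against, since relative to the median gene each of these scores was lower by at least 0.32 under 3 scalings (smallest fall -0.32, for mature neuron genes with the normexp background, exact permutation p = 0.00186, the largest of 9). A dilution of all other cell types alike by a growing cell type is argued against by macrophage and glial scores, which moved apart by 1.44 (exact permutation p = 1.55e-04, the smallest possible). A dilution of neurons, glia, fibroblasts, smooth muscle and endothelium alike stays open. The 6 score differences, from -0.42 for fibroblasts to -0.80 for catecholamine genes, lay within 0.374 of each other, inside the 0.5 set for it (adjusted permutation p = 0.126 for the widest gap). That limit was set after the scores had been seen and is wide beside falls of this size, so it gives little support. In 1 of 15 pairs, looked at later, catecholamine fell more than mature neuron genes (-0.22, exact permutation p = 3.11e-04, adjusted p = 0.00466), which goes against an equal dilution. A difference within the cells of the transgenic ganglion was not tested.

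Among the 8 TH-MYCN SMG, samples with a higher mitosis score had lower scores of catecholamine genes (r = -0.895, exact permutation p = 0.00102), mature neuron genes (r = -0.830, adjusted p = 0.0198 over 7 relations) and glia (r = -0.923, adjusted p = 0.00356), and a higher macrophage score (r = 0.831, adjusted p = 0.0247, but 0.498 without the 2 samples farthest from the median). The slide is argued against as the cause by r = -0.93 after centring within slides (exact within-slide permutation p = 0.00174). A varying share of dividing cells among otherwise unchanged cells would lower every other cell type, and stays open: of 5 cell type scores the fibroblast score had the r with mitosis closest to 0 (r = -0.110, adjusted p = 0.796), neither a rise nor a clear fall. Among pairs of these scores, looked at later, glia minus fibroblasts went most with mitosis (r = -0.879, exact permutation p = 0.00414, adjusted p = 0.0414). An equal lowering of all these cell types would not give that. The pair was picked from many, however, and the other pairs had an adjusted permutation p of 0.159 to 0.900. A difference between mice in how far the ganglion was transformed is a hypothesis that was not tested.

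A sample lay far from the rest of its group in 33 distinct cases, from 416 checks of groups of values. By chance 20.8 of 416 independent checks would do so. The checks repeat genes named in several comparisons, which the 33 count once, and they hold related genes. The 33 and the 20.8 therefore cannot be set against each other. Wild-type SMG 2 had the highest share of spots well above background (65.7%) and the lowest Fbl (1.28). Wild-type SMG 5 stood apart in the nucleotide and polyamine score (1.62), the adrenal cortex score (-4.23) and Impdh2 (3.40). Wild-type SMG 4 did so in Mycl (-2.97) and wild-type SMG 3 in Igfbpl1 (-3.70). TH-MYCN SMG 4 stood apart in Mycn (1.26), Ccnb1 (1.90), Ube2c (2.12), Rrm2 (2.44), Mcm6 (3.18), Shmt1 (-2.19), Ezh2 (0.81) and Pantr1 (-7.51). TH-MYCN SMG 1 did so in the adrenal cortex score (-1.32). Primary sphere 2 stood apart in the erythroid score (-3.67), Hbb-b2 (-4.85), Hbb-bt (-2.63), Hba-a1 (-2.35) and Cldn5 (-5.92). Single values did so in primary spheres 4 (H2-Ab1 -5.96, Aif1 -4.94), 5 (Shmt2 1.83), 6 (Tyrobp -4.28), 7 (Emcn -4.32) and 8 (Pantr1 3.54). Passaged spheres stood apart in the mature neuron score (3.07) and Gpm6a (-2.15) of culture 1, Dbh (7.01) of culture 2, and the mesothelium and epithelium score (-4.99), Aebp2 (2.13) and Mvd (1.66) of culture 3.

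Probes without a gene name here also separated the SMG groups. Of 14854 such probes tested with limma, 3721 were higher and 4145 lower in TH-MYCN SMG than in wild-type SMG, 1412 and 642 of them at least 2-fold.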

How the results depend on the processing

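Fits within slides, the median of tested genes and a median difference of 0 as scalings were chosen after the data had been seen; the other alternatives were not. Over all alternatives, named genes kept their call (higher, lower or none) in 1525 of 1536 cases in TH-MYCN SMG. In primary spheres it was 1855 of 1859, in passaged spheres 1074 of 1159. Gene lists kept theirs in 848 of 884, 792 of 832 and 761 of 806. Of the gene cases, 768, 992 and 480 left out a sample. The largest rises and falls were selected for being called in all of those. Calls of lists ended with the normexp background for mature neuron genes in TH-MYCN SMG (adjusted p = 0.0998, over a range of 2.60e-05 to 0.627 among the alternatives), neural crest (0.103, range 4.82e-08 to 0.331) and amino acid stress genes (0.130, range 2.63e-12 to 0.282) in primary spheres, and nucleotide and polyamine (0.0529, range 0.00385 to 0.251), PRC2 (0.0717, range 7.69e-04 to 0.251) and smooth muscle genes (0.0529, range 4.50e-04 to 0.243) in passaged spheres. These ranges take in fry as well as camera. The lowest values for mature neuron, neural crest, amino acid stress, nucleotide and polyamine, and PRC2 genes came from fry. Fry tests a list against no change, while camera tests it against other genes. Without a filter on dim probes those last 3 and the sympathoadrenal factors in passaged spheres ended (0.243 to 0.251, range 7.94e-04 to 0.280 for the latter). With all 4 groups in one fit the glial list in TH-MYCN SMG (0.220, range 1.03e-05, again from fry, to 0.627) and mitosis in passaged spheres (0.0900, range 4.50e-06 to 0.280) ended. Quantile normalization ended mature neuron genes in TH-MYCN SMG (0.0559) and amino acid stress in primary spheres (0.0926), whose call also ended with a strict filter (just over 0.05) and array weights (0.0602). Among lists called only under an alternative were, in TH-MYCN SMG, fibroblast, smooth muscle and endothelial markers without a filter (0.0218 to 0.0390), smooth muscle with the median difference at 0 (0.0294) and sympathoadrenal factors with normexp (0.0286); in primary spheres, mature neuron genes (0.0278 and 0.0166) and hypoxia and glycolysis (0.0311 and 0.0430) with normexp or quantile normalization, PRC2 without a filter, with array weights, with all 4 groups or with the median difference at 0 (0.0300 to 0.0450), and mesothelium and epithelium with a strict filter (0.0163); and in passaged spheres, hypoxia and glycolysis with normexp or without a filter (0.0328 and 0.0341) and mesenchymal-type, glial and fibroblast lists with all 4 groups (0.0346 each). The causes were not tested. The one gene called in another direction was Th in primary spheres, lower after quantile normalization (-0.90, limma adjusted p = 6.00e-05, range 6.00e-05 to 0.969). The cause was not tested. With normexp, TH-MYCN SMG had 807 genes higher and 365 lower by at least 2-fold, and primary spheres 2120 lower by at least 2-fold. Passaged spheres then had 479 higher (21 by at least 2-fold) and 502 lower (82), 232 genes moved in opposite directions in the 2 sphere comparisons, and replicates agreed at 0.988 in TH-MYCN SMG, 0.994 in primary and 0.992 in passaged spheres; the cause was not tested. With the median difference set to 0, which shifts every gene, TH-MYCN SMG had 4317 lower (255 by at least 2-fold) and primary spheres 1325 higher by at least 2-fold. Without a filter on dim probes, passaged spheres had 4158 higher (614 by at least 2-fold), 1059 genes moved in opposite directions, and replicates agreed at 0.990 in primary and 0.990 in passaged spheres. Of those 4158, 3171 were not tested with the filter, and the genes it removed had a median difference of 0.69. The lowest signal well above background was itself higher on passaged (-5.05 to -4.11) than on primary sphere arrays (-5.56 to -5.22). A rise of genes this dim is therefore not a measured change. Array weights gave 1374 higher (66) and 1452 lower, and 671 in opposite directions; all 4 groups in one fit gave 324 higher and ended the calls of Insm1, Mki67, Plk1, Cdt1, Mcm3, Mcm6, Impdh2, Aebp2, Ezh2 and Lss (limma adjusted p = 0.0640 to 0.513). Quantile normalization ended those of Mki67, Plk1, Impdh2 and Aebp2 (0.0502 to 0.0986). The causes were not tested. For genes named in the report beside an alternative, the limma adjusted p ranged over the alternatives from 0.00623 to 0.806 (Mycn), 1.27e-04 to 0.0884 (Dbh) and 7.47e-06 to 0.203 (Cad) in TH-MYCN SMG, from 0.00232 to 0.121 (Alk) and 4.15e-08 to 0.0856 (Cdk1) in primary spheres, and from 0.00367 to 0.0653 (Mycn), 0.0384 to 0.830 (Myc), 1.81e-07 to 0.333 (Fas), 3.23e-04 to 0.388 (Gdf15), 4.73e-05 to 0.0938 (Selenop) and 1.42e-06 to 0.0795 (Pdgfrb) in passaged spheres. Within slide 3, 274 genes were higher (15) and 14 lists called, and within slide 4, 469 were higher and 490 lower (212), with fewer samples. With the primary spheres divided between the comparisons (5 to 8 in the earlier one), 217 moved in opposite directions. Camera with an estimated correlation called 0 lists in TH-MYCN SMG, 0 in primary spheres and 0 in passaged spheres, and fry called 20 in TH-MYCN SMG. Replicates agreed at 0.924, 0.824, 0.854 and 0.864 in the authors' value table, whose values are centred per probe, and passaged spheres at 0.985 after quantile normalization. Leaving out a sample of the passaged or primary spheres gave 258 to 769 higher genes (258 without passaged sphere 2, 263 without 4, 436 without primary sphere 4, 447 without 7), 20 to 75 by at least 2-fold (20 without passaged sphere 4, 23 without 2, 75 without 1), and 517 to 984 lower (517 without passaged sphere 4, 564 without 2). Dim genes are measured least well in passaged spheres, where 49.0% to 53.9% of spots were well above background.

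Whether the replicate numbers pair the samples was not settled. Same-numbered samples deviated together at a mean r of 0.247 in the SMG (lowest -0.01, and 0.179 for other numbers of one slide). Between primary spheres and TH-MYCN SMG it was 0.031, against -0.004 for other numbers. Between passaged and primary spheres it was 0.095, against -0.014 for other numbers. In these comparisons 4 of 8, 1 of 8 and 3 of 4 samples correlated best with their own number. With the replicate number as a block, 219 genes were higher in passaged spheres (17 by at least 2-fold), 14 lists were called, 168 genes moved in opposite directions, and the calls of 16 named genes in passaged spheres ended, as did that of the glial list in TH-MYCN SMG (adjusted p = 0.0952). Numbers 5 to 8 had no passaged culture, so in passaged spheres this block used primary spheres 1 to 4 only. Those were all on slide 3, so its changes cannot be told apart from leaving out slide 4.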

Other observations

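The genes in this part were chosen after their values had been seen. Mast cell genes were lower in TH-MYCN SMG than in wild-type SMG in 5 of 6 cases, among them Mcpt4 (-2.45), Cma1 (-2.36, above background on 5 of 8 TH-MYCN arrays), Cpa3 (-2.32, SE 0.28, limma adjusted p = 4.23e-06), Tpsb2 (-1.44) and Hdc (-1.05), while Kit differed by -0.08 (limma adjusted p = 0.339). In primary spheres 5 of the 6 were lower than in TH-MYCN SMG, Kit among them, with Mcpt4 at least 12.4-fold, Cpa3 at least 3.16-fold and Cma1 at least 1.27-fold lower, and Tpsb2 differed by 0.17 (limma adjusted p = 0.354). MHC class II genes were lower in TH-MYCN SMG in 6 of 7 cases, for example Cd74 (-0.78), H2-Aa (-0.68) and H2-Eb1 (-0.66), beside macrophage markers that rose. In spheres H2-Eb1 was at least 479-fold, H2-Aa at least 47.7-fold and H2-DMb1 at least 41.8-fold lower. All 9 genes of MHC class I and its peptide supply were lower in both comparisons. In TH-MYCN SMG they included Tapbp (-0.92), Tap1 (-0.88), Psmb8 (-0.75) and H2-K1 (-0.72), and in primary spheres H2-K1 (-3.63), B2m (-3.04), Psmb8 (at least 86.5-fold) and Tap1 (at least 4.05-fold). In passaged spheres H2-K1 (-0.94, limma adjusted p = 0.00931) and H2-D1 (-0.89, limma adjusted p = 0.0114) were lower still.

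Genes of early neuronal differentiation were higher in TH-MYCN SMG than in wild-type SMG in 8 of 11 cases and lower in 1, Dll3 (-0.84). Neurod6 was at least 34.6-fold, Nhlh2 at least 12.5-fold and Neurod1 at least 2.51-fold higher, with Dll1 (2.92) and Dcx (2.59) beside them. In primary spheres 4 of the 11 were higher, such as Dcx (1.12) and Stmn1 (0.94), and 5 lower, such as Igfbpl1 (-2.38) and Nhlh2 (at least 9.78-fold). Of 9 neuropeptide genes, Cartpt was higher in TH-MYCN SMG than in wild-type SMG (4.19) and higher again in primary spheres (4.82), whereas Sst (-1.17, then at least 26.3-fold lower) and Gal (-0.97, then -3.86) were lower in both, and Pnoc, far higher in TH-MYCN SMG, was lower in spheres (-6.48). Passaged spheres had less Adcyap1 (-1.89) than primary spheres. Among neurotrophins and their receptors, Bdnf (5.10), Ntf3 (2.23, above background on 1 of 8 wild-type arrays) and Gfra3 (0.86) were higher and Ngfr (-1.15) and Ret (-0.92) lower in TH-MYCN SMG. In primary spheres Ret (1.23) was higher and Gfra2 (-1.81) lower, and in passaged spheres Bdnf was higher (0.43) and Ngfr (-1.52) and Ntf3 (-1.13) lower.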
